A study of Homo sapiens with 16 samples.

How the data were processed

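RNA of SAOS cells was hybridised to 16 Affymetrix expression arrays of 1 design, 1 sample per array. Per the labels, 4 arrays came from cells without transfection, 4 from cells transiently transfected with human RB, 4 from cells transfected with mouse SMYD2 and 4 from cells transfected with both. The labels name no arm with an empty vector. The arrays of each group carry the replicate numbers 1, 3, 4 and 5. Nothing in the labels says that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

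The deposited values are log2 signals of 54675 probe sets per array, all from 1 table. They were made with RMA (background correction, quantile normalization and a summary of the probes of each set), per the submitters' processing notes, which state no version. Whether all 16 arrays were normalized together is not given in the sources used here. The array medians lay between 5.59 and 5.64, and pairs of arrays of 1 group correlated at 0.981 to 0.998 over all probe sets, with at most 0.0750% of values identical. No array was therefore treated as a copy of another. RMA keeps no detection call, so a low signal was not separated from background, and the number of arrays limits the precision.

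Gene names came from the platform annotation given with the table. Of the probe sets, 41097 carried 1 gene symbol, 1801 carried several and 11777 carried none. Of the 41097, 41043 matched a gene of the human RefSeq annotation, and 0 symbols were changed. Each gene was represented by its probe set with the highest mean over all 16 arrays, which left 19775 genes. Probe sets with several symbols or none were tested apart and name no gene here. No coordinates are given, because the sources used here name no genome build.

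Differences between groups were tested on the log2 values with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per group over all 16 arrays, then eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Adjusted p-values below are limma's unless another test is named. Errors are standard errors of that fit for differences and SD for group values, with n = 4 per group. There were 7 comparisons, of which 1 was the interaction, the difference made by RB with SMYD2 minus that without it. Median shifts of all genes between groups were at most 0.02 on the log2 scale.

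A set of 29 gene lists was fixed before the data were examined. They cover the cell cycle, histones, DNA repair, stress responses, metabolism, osteoblast genes, the SMYD family and markers of other cell types. Each list was tested with limma's camera with a preset correlation between genes of 0.01, adjusted over the 29 lists, and again with the correlation estimated from the data. Members were counted as rising or falling at the adjusted p over all 19775 genes, and also when adjusted over the list alone. Replication-dependent histone genes form families of similar sequence, and their probe sets can share targets.

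The genes named were set by a rule fixed before the data were examined. It takes RB1, SMYD2 and L3MBTL1 everywhere and a fixed set of cell cycle genes. In RB against control, SMYD2 against control and RB plus SMYD2 against RB it takes the 10 largest increases and decreases that passed the test and whose groups did not overlap. In the other comparisons it takes 5 each way. Where no gene passed, it takes the 5 with the smallest p. From each list discussed, it takes the 4 members with the largest absolute difference.

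Whether equal replicate numbers pair arrays of different groups was checked from the correlation of their deviations from the group means. For control with each of the other groups, RB with RB plus SMYD2, and SMYD2 with RB plus SMYD2, each same-numbered pair correlated above 0.1, the lowest at 0.145. A fit with the replicate number as a block is therefore given beside those results where it changes a call or a count by over 1.5 times.

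The fit was tested on simulated data with the real genes, means and spreads and 200 changed genes. For RB against control it recovered 64.0% of 100 genes changed by 0.5 on the log2 scale and 96.0% of 100 changed by 1. There were 14 false calls among the genes left unchanged. For RB plus SMYD2 against RB these were 59.0%, 97.0% and 8. The simulated noise was independent between genes and arrays, with no replicate-number structure and no array of lower quality. These rates may therefore not carry over to the real arrays. Alternatives covered the scaling, the choice of probe set, filters on dim genes, the samples in the fit, array weights, the replicate block and each array left out. Figures were drawn with matplotlib 3.10.9.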

Results

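The study asked what overexpressed SMYD2, a lysine methyltransferase that can methylate RB, does to ectopic RB in SAOS cells. SAOS is an established human osteosarcoma line that lacks functional RB, the retinoblastoma protein, which holds back the E2F transcription factors that drive entry into S phase. Transcript levels were measured on 16 arrays. The 4 groups were untransfected control cells, cells given human RB, cells given mouse SMYD2, and cells given both, with 4 arrays each. All values are log2 signals.

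The transfected RB was visible in 1 of the 2 RB1 probe sets. The brighter set read 6.48 ± 0.32 (SD, n = 4) in control, 6.85 ± 0.17 with SMYD2, 7.70 ± 0.34 with RB and 8.67 ± 0.90 with RB plus SMYD2. RB exceeded control by 1.22, with no overlap of the arrays (exact two-sided permutation p = 0.0286, the smallest that 4 arrays against 4 allow). RB plus SMYD2 exceeded SMYD2 by 1.82, again without overlap (exact permutation p = 0.0286). RB1 read 0.97 ± 0.31 (SE) more with RB plus SMYD2 than with RB alone and was higher in 4 of 4 same-numbered pairs, but the groups overlapped (exact permutation p = 0.114). The dimmer RB1 probe set stayed between 3.43 and 3.51 in the group means, so it carried no sign of the construct. SMYD2 itself differed little. Its brightest probe set read 10.16 ± 0.05 in control and 10.28 ± 0.07 with SMYD2 (exact permutation p = 0.0571), and was higher in 4 of 4 same-numbered pairs. A dimmer SMYD2 probe set differed by -0.14 and was higher in 0 of 4. The transfected SMYD2 was mouse, and human probes may not bind it, so these readings do not check the label. L3MBTL1, a chromatin protein that binds methylated lysines, differed by -0.02 ± 0.09 between RB and control in its brightest probe set (limma adjusted p = 0.959). Its dimmer probe sets differed by -0.33 and -0.16 (exact permutation p = 0.0571 for each), and by -0.02, 0.05 and 0.003.

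**Figure D1:**
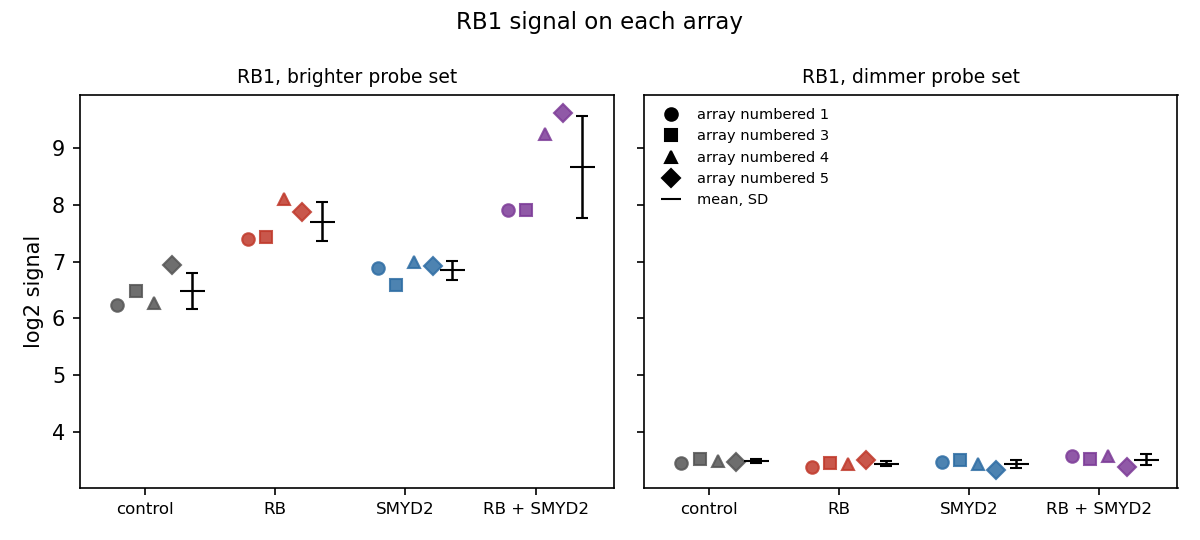
RB1 signal (log2) on each array for the brighter probe set (left) and the dimmer one (right), by group; marker shapes give the array number, and black bars give the mean and SD of 4 arrays. The brighter set lies highest with RB plus SMYD2 (mean 8.67), where the arrays spread from 7.90 to 9.62.

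RB against control addressed what ectopic RB does to these cells. The control cells were not transfected, so each difference from control includes any effect of transfection itself. Genes of DNA replication and mitosis fell together, and a group of histone genes rose. KIF14, a mitotic kinesin, fell by 0.95 ± 0.17 on the log2 scale (1.93-fold), SGO2, a protector of centromeric cohesion, by 0.86 ± 0.11, and NUF2, a kinetochore protein, by 0.78 ± 0.12. The histone genes H2BC4, H4C8 and H2BC21 rose 3.10-fold, 2.66-fold and 2.39-fold. Across 19775 genes, limma called 585 at an adjusted p under 0.05, 246 higher and 339 lower with RB. Of these, 17 differed by at least 1 on the log2 scale, and all 17 were higher.

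Among 46 genes of G2/M and mitosis, 38 fell and 8 did not pass, and 46 fell when adjusted over the list alone. Their median difference was -0.71 (camera adjusted p = 9.5e-64, and adjusted p = 0.0110 with an estimated correlation). CENPE, a kinetochore motor, fell by 0.89 ± 0.23 and ASPM, a spindle pole protein, by 0.83 ± 0.19. Among 55 genes of G1/S and DNA replication, 35 fell and 20 did not pass, with 52 falling when adjusted over the list alone. Their median was -0.53 (camera adjusted p = 2.3e-51, and adjusted p = 0.00334 with an estimated correlation). CHAF1A, a subunit of the chromatin assembly factor that follows the replication fork, fell by 0.71 ± 0.12. The repressor E2Fs E2F7 and E2F8 fell by 0.70 ± 0.13 and 0.69 ± 0.15. MCM10, a replication initiation factor, differed by -0.70 ± 0.26 and did not pass, but did with the replicate block (limma adjusted p = 0.205, 0.0174 with the block and 0.0490 without SMYD2 array 1). Of 23 genes of homologous recombination and Fanconi repair, 8 fell and 14 did when adjusted over the list alone, with a median of -0.49 (camera adjusted p = 3.4e-17, and adjusted p = 0.0110 with an estimated correlation). FANCI fell by 0.70 ± 0.09, RAD51AP1 by 0.71 ± 0.18, BRIP1 by 0.69 ± 0.15 and the helicase gene BLM by 0.68 ± 0.13. With each of the 16 arrays left out in turn, CENPE lost its call in 13 cases and RAD51AP1 in 11, so both were marginal throughout (limma adjusted p up to 0.156 without control array 5 and 0.138 without RB array 4). ASPM lost it in 4, E2F8 in 3 and BRIP1 in 3 (limma adjusted p up to 0.0756 without control array 5, 0.0602 without control array 4 and 0.0765 without RB array 4).

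Of the fixed cell cycle genes, TK1 and TYMS, enzymes of thymidylate supply, fell by 0.68 ± 0.14 and 0.62 ± 0.10. CCNA2, the cyclin of S phase and G2, fell by 0.71 ± 0.15, RRM2 by 0.60 ± 0.16, PCNA by 0.50 ± 0.10, MCM2 by 0.44 ± 0.10, CCNE2 by 0.57 ± 0.13 and E2F1 by 0.44 ± 0.09. RBL1, the RB relative p107, fell by 0.62 ± 0.12, although only 2 of its 4 probe sets went that way. CDC6, MCM5 and CDK1 differed by -0.50 ± 0.22, -0.46 ± 0.20 and -0.60 ± 0.23 and did not pass. In the fit with the replicate block, MCM5 and CDK1 passed (limma adjusted p = 0.00179 and 0.0416), as did CCND1 at 0.60 ± 0.21 (limma adjusted p = 0.0159). CDK1 also passed without SMYD2 array 1 (limma adjusted p = 0.0279). CCNE1, CDKN1A and CDKN1B differed by -0.20 ± 0.16, -0.10 ± 0.16 and -0.18 ± 0.08 and passed in neither fit. Among the 7 measured CDK inhibitors, CDKN2B rose by 0.85 ± 0.18 and CDKN3, a phosphatase that peaks in mitosis, fell by 0.71 ± 0.09. With each of the 16 arrays left out in turn, RRM2 lost its call in 12 cases, CCNE2 and MCM2 in 4 each, CCNA2 in 2 and TK1 in 1. The highest limma adjusted p was 0.165 for RRM2 without control array 5, 0.0774 for CCNE2 without RB array 4, and 0.0667, 0.0515 and 0.0557 for MCM2, CCNA2 and TK1 without control array 4.

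Among the other large decreases, SPC25, a kinetochore subunit, fell by 0.86 ± 0.14, TROAP by 0.83 ± 0.09, DEPDC1B by 0.79 ± 0.14, the condensin subunit gene NCAPD2 by 0.79 ± 0.10 and KIF23, a kinesin of cytokinesis, by 0.78 ± 0.18. KIF23 lost its call in 5 of 16 cases with 1 array left out (limma adjusted p up to 0.0847, without RB array 4). Of the 339 genes called lower, 81 belonged to the 124 genes of the 3 lists above.

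Of 17 replication-dependent histone genes, 7 rose and 10 did not pass, and adjusted over the list alone 7 rose and 1 fell. The median was 0.30 (camera adjusted p = 8.1e-08, but adjusted p = 0.164 with an estimated correlation). H2BC4 rose by 1.63 ± 0.28, H4C8 by 1.41 ± 0.21, H2BC21 by 1.25 ± 0.12 and H1-2 by 1.13 ± 0.22. The remaining large increases were of genes with varied roles. CRYBA2, a lens crystallin, rose by 1.77 ± 0.39, the ectonucleotidase gene ENTPD3 by 1.38 ± 0.31, PTGES, a prostaglandin E synthase, by 1.22 ± 0.12, the monocarboxylate carrier gene SLC16A4 by 1.21 ± 0.22 and IGDCC4 by 1.21 ± 0.26. RB1 was called as well (limma adjusted p = 0.0414). With each of the 16 arrays left out in turn, RB1 lost its call in 8 cases, ENTPD3 in 6, CRYBA2 in 5 and IGDCC4 in 2. The highest limma adjusted p was 0.154 for RB1 without RB array 4, 0.0952 for ENTPD3 without control array 4, and 0.0748 and 0.0615 for CRYBA2 and IGDCC4 without control array 5.

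Of 26 osteoblast differentiation genes, 3 rose and 5 did when adjusted over the list alone. OMD, a keratan sulphate proteoglycan of bone, rose by 1.26 ± 0.21, SPARC by 0.81 ± 0.16 and SPP1, the gene of osteopontin, by 0.83 ± 0.16, the last in 1 of 2 probe sets. COL1A2 differed by 0.94 ± 0.52 and did not pass, but did with the replicate block (limma adjusted p = 2.1e-05). The list's median was 0.15 (camera adjusted p = 0.000172, but adjusted p = 0.101 with an estimated correlation; 0.0227 with the block and an estimated correlation). Among 36 genes of the extracellular matrix and adhesion, 3 rose, over all genes and over the list alone, and the median was 0.22 (camera adjusted p = 4.0e-05, and adjusted p = 0.0301 with an estimated correlation). Its members with the largest differences, COL6A2 at 0.72 ± 0.24, COL12A1 at 0.72 ± 0.32, THBS1 at 0.68 ± 0.62 and COL3A1 at 0.60 ± 0.31, did not pass, although COL12A1 did with the block (limma adjusted p = 0.0350) and COL6A2 without control array 3 (0.0173). Among 27 genes of lysosome and autophagy, 4 rose, and adjusted over the list alone 10 rose and 1 fell, with a median of 0.18 (camera adjusted p = 1.0e-06, but adjusted p = 0.124 with an estimated correlation). WIPI1 rose by 0.71 ± 0.11, LAMP2 by 0.45 ± 0.11 and BECN1 by 0.44 ± 0.08, the last in 2 of 3 probe sets, while CTSB differed by 0.44 ± 0.13 and passed only without RB array 1 (limma adjusted p = 0.0388). Of 21 hypoxia-induced genes, 4 rose, STC2 (0.80 ± 0.18), NDRG1 (0.58 ± 0.14) and MXI1 (0.43 ± 0.09) among them, while DDIT4 at 0.46 ± 0.18 did not pass. That list's shift was lost with an estimated correlation (camera adjusted p = 0.00330 against an adjusted p = 0.547). Of 31 genes of the unfolded protein and amino acid responses 2 rose, HERPUD1 by 0.53 ± 0.10, while DDIT4, DNAJB9 (0.45 ± 0.19) and CHAC1 (0.36 ± 0.16) did not pass (camera adjusted p = 0.0286, but adjusted p = 0.547 with an estimated correlation). DNAJB9 and CHAC1 passed with the block (limma adjusted p = 0.0333 and 0.0309). With each of the 16 arrays left out in turn, LAMP2 lost its call in 6 cases, STC2 and NDRG1 in 5 each, MXI1 in 3 and SPARC in 1. The differences in the case with the highest limma adjusted p stayed close: 0.40 for LAMP2, 0.40 for MXI1 and 0.71 for SPARC without control array 4 (limma adjusted p = 0.113, 0.0758 and 0.0514), 0.79 for STC2 without control array 5 (0.0678) and 0.55 for NDRG1 without RB array 4 (0.112).

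The count for RB against control depended on single arrays and on the pairing. It was 1399 with the replicate block (713 higher, 686 lower), 286 without RB array 4, 290 without control array 4, 318 without control array 5, 347 without RB array 5 and 984 without SMYD2 array 1.

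**Figure D2:**
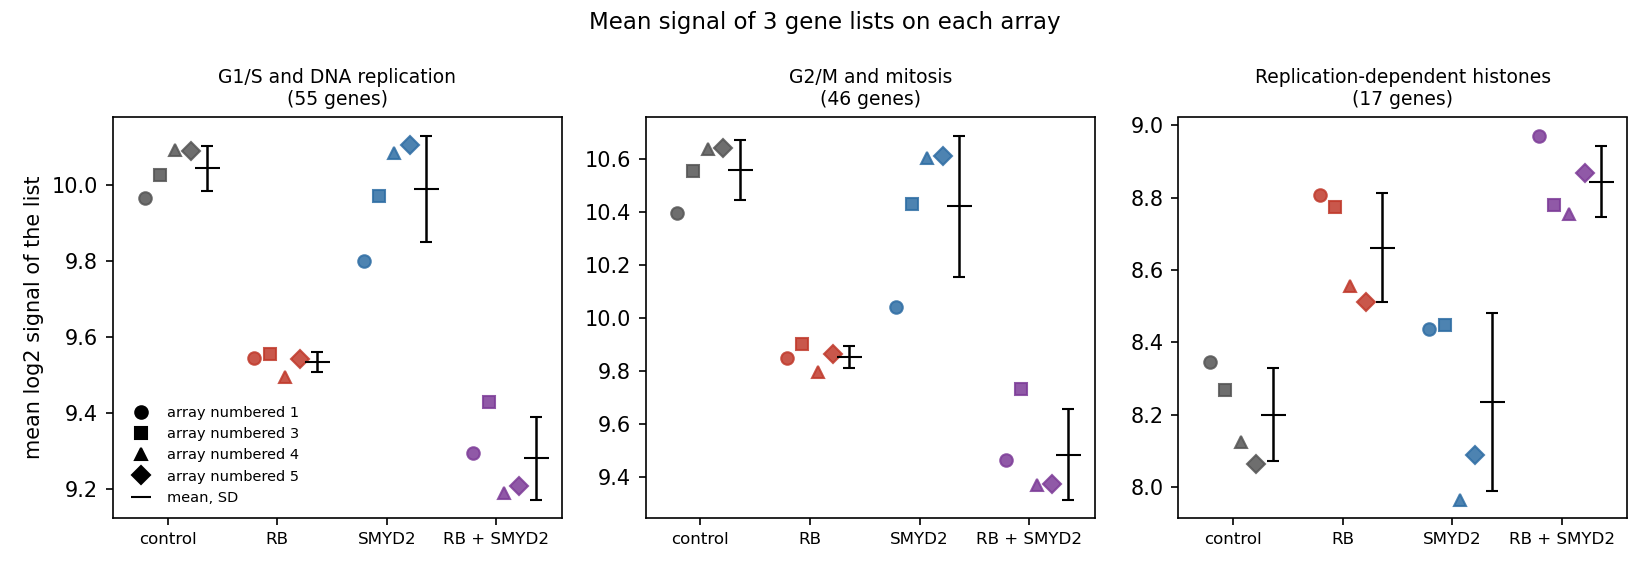
Mean log2 signal of 3 gene lists on each of the 16 arrays, by group; marker shapes give the array number, and black bars give the mean and SD of 4 arrays. The G2/M mean was 10.56 in control, 9.85 with RB, 10.42 with SMYD2 and 9.48 with RB plus SMYD2, and the histone list ran the other way, from 8.20 in control to 8.84 with both.

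SMYD2 against control addressed what SMYD2 does without ectopic RB. No gene passed. Limma called 0 of 19775 genes (572 at an unadjusted p under 0.05, 2.89% of those tested, with a smallest adjusted p of 0.991), and 0 with the replicate block (868 unadjusted). By chance about 989 of the genes would have an unadjusted p under 0.05. Both fits lay below that, so the absence of calls does not show that SMYD2 had no effect. The 5 genes with the smallest p were MAGI2-AS2 (0.37 ± 0.09), PAK5 (0.28 ± 0.07), C5orf47 (0.42 ± 0.10), TMEM182 (0.34 ± 0.08) and LTBP2 (0.34 ± 0.09). The other probe sets of PAK5, C5orf47 and LTBP2 had the opposite sign. RB1, SMYD2 and L3MBTL1 differed by 0.36 ± 0.31, 0.11 ± 0.08 and 0.12 ± 0.09.

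The cell cycle lists lay slightly lower with SMYD2, with 0 members called in any of them. The median of the G2/M list was -0.13 (camera adjusted p = 1.7e-06), that of the G1/S list -0.05 and that of the repair list -0.08 (camera adjusted p = 0.0295 for both), and that of the unfolded protein list -0.03 (camera adjusted p = 0.0496). With an estimated correlation the adjusted p was 0.926 for each. With the replicate block, TGF-beta targets and oxidative phosphorylation were called too (camera adjusted p = 0.0476 and 0.0252, but adjusted p = 0.833 for both with the block and an estimated correlation). In the G2/M list ANLN, CENPE, KIF14 and ECT2 differed by -0.38 ± 0.25, -0.33 ± 0.23, -0.32 ± 0.17 and -0.31 ± 0.17. SMYD2 array 1 carried much of this shift. Its ratio of 3′ to 5′ ACTB signal, a measure of RNA integrity, was 3.53 on the log2 scale, against 0.54 to 2.46 on the other arrays, and the SMYD2 group averaged 1.62 ± 1.34 against 1.17 ± 0.89 in control. Without that array 0 lists were called, against 4 with it, 7 without control array 1 and 1 without control array 5.

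RB plus SMYD2 against RB was the comparison of the series title, what SMYD2 adds when RB is present. No single gene passed, but the cell cycle lists lay lower still. All 46 genes of the G2/M list had negative differences, with a median of -0.38, and 29 of them fell when adjusted over the list alone. Among 55 G1/S and DNA replication genes, all had negative differences, with a median of -0.26, and 9 fell when adjusted over the list alone. Of 23 repair genes, 21 were lower, with a median of -0.20, and 2 fell when adjusted over the list alone. Over all 19775 genes limma called 0 (856 at an unadjusted p under 0.05, 4.33% of those tested, smallest adjusted p 0.552), and 0 with the replicate block (1236 unadjusted). Chance would give about 989 at that unadjusted p, so the fit without the block lay below it and the fit with the block above.

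The mean of the G2/M list was 9.48 ± 0.17 (SD, n = 4) with both constructs and 9.85 ± 0.04 with RB, and that of the G1/S list was 9.28 ± 0.11 against 9.53 ± 0.03. Both were lower in 4 of 4 same-numbered pairs, with differences of -0.49 to -0.17 for G2/M and -0.33 to -0.13 for G1/S. The 4 arrays of each group did not overlap (exact two-sided permutation p = 0.0286 for each, the smallest possible, and 0.207 adjusted over the 29 lists). Camera gave an adjusted p of 2.2e-52 for G2/M, 1.1e-33 for G1/S and 2.8e-11 for repair. With an estimated correlation the adjusted p was 0.0339, 0.0204 and 0.0475. With the replicate block and an estimated correlation it was 0.0848, 0.0848 and 0.171, so those calls were lost. Replication-dependent histones had a median of 0.12 (camera adjusted p = 0.000172, but adjusted p = 0.716 with an estimated correlation), with 1 member rising when adjusted over the list alone. With the block, TGF-beta targets and the unfolded protein list were called too (camera adjusted p = 0.0238 and 0.0186, but adjusted p = 0.393 for both with an estimated correlation as well). Without RB array 5, 7 lists were called in place of 4.

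HMMR, a spindle assembly factor, had the smallest p and differed by -0.44 ± 0.08, followed by FANCI (-0.47 ± 0.09), TACC3, a spindle protein (-0.40 ± 0.08), CKS2, a CDK-binding protein (-0.30 ± 0.06) and the noncoding RNA LINC01348 (0.29 ± 0.06). Limma's adjusted p was 0.552 for the first 4 and 0.685 for the last. In the G2/M list BUB1 differed by -0.47 ± 0.14, AURKA by -0.46 ± 0.11, KIF4A by -0.46 ± 0.12 and FOXM1, a transcription factor of mitotic genes, by -0.45 ± 0.11. In the G1/S list CLSPN differed by -0.55 ± 0.20, MCM10 by -0.52 ± 0.26, E2F8 by -0.47 ± 0.15 and CDC6 by -0.44 ± 0.22. In the repair list CHEK1, RAD54B and FANCM differed by -0.36 ± 0.18, -0.35 ± 0.17 and -0.32 ± 0.18. Among the histones H2AC8, H4C8, H2BC21 and H1-2 differed by 0.50 ± 0.20, 0.50 ± 0.21, 0.43 ± 0.12 and 0.41 ± 0.22. The fixed genes RRM2, CCNA2 and TK1 differed by -0.41 ± 0.16, -0.39 ± 0.15 and -0.31 ± 0.14, E2F1 by -0.01 ± 0.09, CDKN1A by 0.07 ± 0.16 and CCND1 by 0.00 ± 0.21. SMYD2 and L3MBTL1 differed by 0.13 ± 0.08 and 0.13 ± 0.09, and RB1 by 0.97, higher in 4 of 4 same-numbered pairs. None of these genes passed.

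RB plus SMYD2 against SMYD2 gave the difference made by RB in the presence of SMYD2. H2BC4, H4C8 and H2BC21 rose by 1.92 ± 0.28, 1.84 ± 0.21 and 1.67 ± 0.12, RB1 by 1.82 ± 0.31 and SLC16A4 by 1.70 ± 0.22. TROAP fell by 1.24 ± 0.09 (2.36-fold), the kinetochore genes SKA1, SPC25 and SPC24 by 1.23 ± 0.13, 1.21 ± 0.14 and 1.19 ± 0.12, and the meiotic recombination gene MND1 by 1.22 ± 0.11. SPC24 fell in 1 of its 2 probe sets. Limma called 1422 of 19775 genes, 582 higher and 840 lower, of which 33 and 47 differed by at least 1.

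The cell cycle lists fell nearly whole. Of 46 G2/M genes 42 fell and 46 did over the list alone (median -0.95, camera adjusted p = 1.7e-61, and adjusted p = 0.0126 with an estimated correlation), with FOXM1, CDC20, AURKA and ASPM at -1.16 ± 0.11, -1.15 ± 0.11, -1.15 ± 0.11 and -1.12 ± 0.19. Of 55 G1/S genes 49 fell and 53 did over the list alone (median -0.72, camera adjusted p = 1.5e-54, and adjusted p = 0.00254 with an estimated correlation), with MCM10, E2F8 and E2F7 at -1.01 ± 0.26, -0.99 ± 0.15 and -0.99 ± 0.13. Of 23 repair genes 15 fell and 17 did over the list alone (median -0.66, camera adjusted p = 1.1e-16, and adjusted p = 0.0126 with an estimated correlation, 0.0522 with the block as well), with FANCI at -1.05 ± 0.09 and RAD54L at -0.96 ± 0.09. Of 17 histones 7 rose and 1 fell (median 0.42, camera adjusted p = 2.7e-08, but adjusted p = 0.167 with an estimated correlation). In the matrix list 7 of 36 genes rose and 1 fell (median 0.34, camera adjusted p = 5.7e-06, and adjusted p = 0.0169 with an estimated correlation), COL6A2 by 1.01 ± 0.24 and COL6A1 by 0.78 ± 0.12. In the lysosome list 9 of 27 genes rose and 1 fell (median 0.23, camera adjusted p = 4.9e-06, but adjusted p = 0.167 with an estimated correlation), WIPI1 and LAMP2 by 0.94 ± 0.11 and 0.69 ± 0.11. The osteoblast list (median 0.28, 4 rose), hypoxia (0.15, 4 rose), unfolded protein (0.07, 2 rose and 1 fell) and ribosome biogenesis lists (-0.03, 4 fell) had camera adjusted p = 0.00352, 0.00838, 0.0493 and 0.0493, and adjusted p = 0.184, 0.574, 0.574 and 0.574 with an estimated correlation. With the block the ribosome biogenesis list was lost (camera adjusted p = 0.0662), and the osteoblast list held with an estimated correlation (adjusted p = 0.0467). OMD rose by 1.63 ± 0.21 and CDKN2B by 1.17 ± 0.18, while CDKN3 fell by 1.11 ± 0.09. Of the fixed genes CDC6, MCM5, TK1, RRM2 and CCNA2 fell by 0.87 ± 0.22, 0.82 ± 0.20, 0.95 ± 0.14, 0.93 ± 0.16 and 0.88 ± 0.15. CDK1, CCNE1 and CCND1 differed by -0.60 ± 0.23, -0.43 ± 0.16 and 0.48 ± 0.21 and did not pass, but did with the block (limma adjusted p = 0.0243, 8.6e-04 and 0.0325), CDK1 also without SMYD2 array 1 (0.00187). The count was 2812 with the replicate block, 859 without RB plus SMYD2 array 4 and 904 without its array 5. With each of the 16 arrays left out in turn, MCM10 lost its call in 5 cases, CDC6 in 4, and MCM5 and COL6A2 in 2 each. The highest limma adjusted p was 0.0766 for CDC6 and 0.0550 for COL6A2 without RB plus SMYD2 array 4. It was 0.0768 for MCM5 without array 5 of that group and 0.0779 for MCM10 without SMYD2 array 4.

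The RB difference was set against itself with and without SMYD2, 2 contrasts that share no array. Across 19775 genes, which are not independent replicates, the 2 differences correlated at r = 0.807 (Spearman rho 0.626). Called in both were 193 higher and 332 lower genes, against 7.24 and 14.4 for independent lists, and 0 genes went opposite ways. Of the 585 genes called without SMYD2, 583 had the same sign with it and 455 had the larger difference there. Of the 1422 genes called with SMYD2, 1336 had the smaller difference without it. Genes selected in 1 contrast are pulled toward 0 in the other, so the 1336 of 1422 do not test a difference. The 455 of 585 run against that pull. Since genes are not independent replicates, that share is described only and does not test a difference either.

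**Figure D3:**
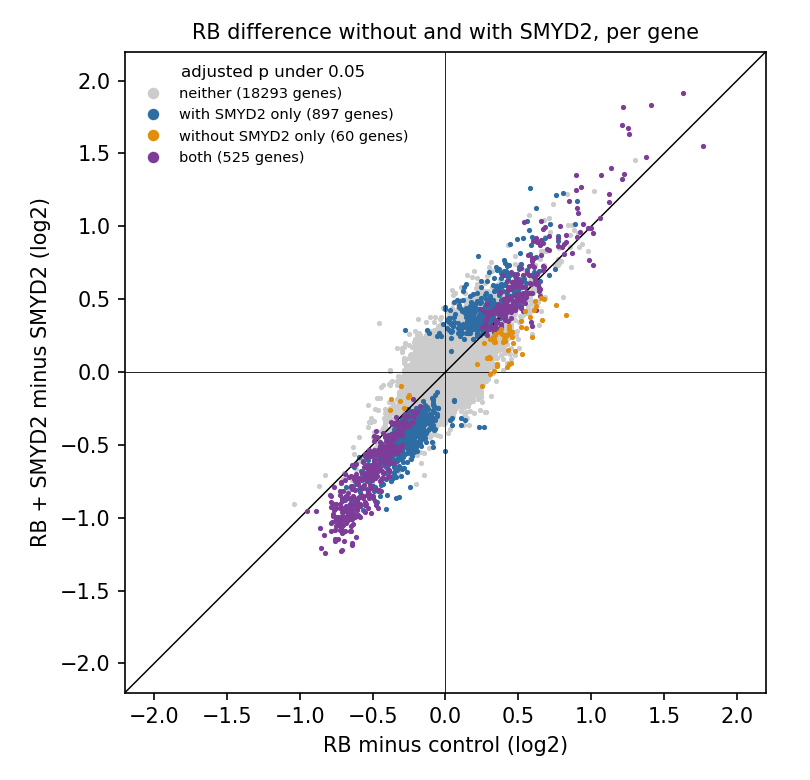
RB minus control (x axis, log2) against RB plus SMYD2 minus SMYD2 (y axis, log2) for 19775 genes, coloured by which comparison called them; the diagonal marks equal differences. The 525 genes called in both have the same sign in both, and 897 were called with SMYD2 present and not without it.

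The interaction tested whether that RB difference changed with SMYD2. Limma called 0 of 19775 genes (582 at an unadjusted p under 0.05, none with an adjusted p below 0.999). Chance would give about 989 at that unadjusted p, so the absence of calls does not show the absence of an interaction. The cell cycle lists leaned toward a larger decrease with SMYD2, with medians of -0.25 for G2/M (camera adjusted p = 9.7e-16), -0.21 for G1/S (1.4e-12 by camera) and -0.14 for repair (0.00843 by camera), while histones stood at 0.13 (0.0353 by camera). With an estimated correlation the adjusted p was 0.687, 0.529, 0.687 and 0.979, so none of the 4 held. The largest members were CDCA3, AURKA, FOXM1 and KIF2C at -0.45 ± 0.17, -0.41 ± 0.15, -0.40 ± 0.15 and -0.40 ± 0.13. The 5 genes with the smallest p were CPLX2 (0.57 ± 0.12), PSTPIP2 (-0.61 ± 0.14), MIF-AS1 (-0.64 ± 0.15), LOC101929657 (-0.38 ± 0.09) and MAGI2-AS2 (-0.50 ± 0.12). RB1, SMYD2 and L3MBTL1 stood at 0.60 ± 0.44, 0.02 ± 0.11 and 0.01 ± 0.13. Without SMYD2 array 5, 2 lists were called in place of 4.

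RB plus SMYD2 against control set both constructs against untransfected cells. RB1 rose by 2.19 ± 0.31, H4C8 by 1.91 ± 0.21, CRYBA2 by 1.88 ± 0.39, H2BC4 by 1.72 ± 0.28 and H2BC21 by 1.68 ± 0.12. CENPE, SKA1, SPC25, KIF14 and ASPM fell by 1.29 ± 0.23, 1.28 ± 0.13, 1.28 ± 0.14, 1.27 ± 0.17 and 1.24 ± 0.19. All 46 G2/M genes fell (median -1.09, camera adjusted p = 1.2e-76, and adjusted p = 0.00531 with an estimated correlation), and 52 of 55 G1/S genes did (median -0.79, camera adjusted p = 4.1e-64, and adjusted p = 0.00119 with an estimated correlation). Of 23 repair genes 16 fell, FANCI by 1.17 ± 0.09 (median -0.69, camera adjusted p = 5.3e-22, and adjusted p = 0.00531 with an estimated correlation). Of 17 histones 7 rose and 1 fell (median 0.41, camera adjusted p = 2.5e-09, but adjusted p = 0.151 with an estimated correlation). Collagen VI and V genes rose, COL6A2 by 1.18 ± 0.24, COL6A1 by 0.95 ± 0.12 and COL5A1 by 0.66 ± 0.11, while FBLN1 fell by 0.63 ± 0.16 in 3 of 5 probe sets (matrix list median 0.21, camera adjusted p = 8.7e-04, but adjusted p = 0.0860 with an estimated correlation). FBLN1 lost its call in 4 of 16 cases with 1 array left out (limma adjusted p up to 0.0808, without control array 4). In the lysosome list 8 genes rose and 1 fell (median 0.24, camera adjusted p = 6.3e-06, but adjusted p = 0.169 with an estimated correlation), and in the osteoblast list 4 rose (median 0.20, camera adjusted p = 0.00668, but adjusted p = 0.229 with an estimated correlation). With the block, heat shock genes were called (camera adjusted p = 0.0244, but adjusted p = 0.516 with an estimated correlation as well), and CCNE1 at -0.37 ± 0.16 and CCND1 at 0.60 ± 0.21 passed (limma adjusted p = 0.00270 and 0.00900), CCND1 also without RB array 3 (0.0203). Limma called 1424 genes, 594 higher and 830 lower, of which 34 and 93 differed by at least 1. The count was 2562 with the replicate block, 899 and 925 without RB plus SMYD2 arrays 4 and 5, and 949 without control array 4.

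RB against SMYD2 had a transfection on both sides, which the comparisons with untransfected cells do not. H2BC4, SLC16A4, H4C8, LRRC15 and OMD rose by 1.83 ± 0.28, 1.59 ± 0.22, 1.34 ± 0.21, 1.31 ± 0.18 and 1.25 ± 0.21 with RB. TROAP, SGO2, PHF19, C1QTNF2 and SPC25 fell by 0.97 ± 0.09, 0.87 ± 0.11, 0.85 ± 0.10, 0.82 ± 0.13 and 0.79 ± 0.14. Of 46 G2/M genes 29 fell (median -0.58, camera adjusted p = 2.2e-40, and adjusted p = 0.0499 with an estimated correlation), and of 55 G1/S genes 29 fell (median -0.47, camera adjusted p = 1.5e-36, and adjusted p = 0.0146 with an estimated correlation). Of 17 histones 5 rose and 1 fell (median 0.23, camera adjusted p = 2.6e-06, but adjusted p = 0.235 with an estimated correlation). Repair genes had a median of -0.34 with 7 of 23 falling, and matrix genes 0.30 with 3 of 36 rising (camera adjusted p = 3.6e-10 and 6.2e-07, and adjusted p = 0.0499 and 0.0168 with an estimated correlation). The osteoblast (0.22), unfolded protein (0.18), hypoxia (0.22) and lysosome (0.20) lists were shifted as well, with 4, 2, 4 and 5 genes rising. With an estimated correlation those calls were lost (adjusted p = 0.101, 0.188, 0.289 and 0.150). E2F1, MCM2, PCNA, TK1 and TYMS fell by 0.53 ± 0.09, 0.51 ± 0.10, 0.40 ± 0.10, 0.64 ± 0.14 and 0.47 ± 0.10. The fixed genes RBL1, CCNE2, CCNA2, RRM2 and CDC6 did not pass (limma adjusted p = 0.0546, 0.0746, 0.0851, 0.0859 and 0.351). Without SMYD2 array 1, CCNE2, CCNA2, RRM2 and CDC6 passed (limma adjusted p = 0.0217, 0.00372, 0.00358 and 0.0327). RB1 differed by 0.86 ± 0.31 and did not pass over all genes (limma adjusted p = 0.162), although its arrays did not overlap (exact permutation p = 0.0286). Limma called 642 genes, 274 higher and 368 lower, and 304, 400 and 415 without RB arrays 4, 3 and 5. With each of the 16 arrays left out in turn, PCNA lost its call in 5 cases, and TK1 and TYMS in 3 each. The highest limma adjusted p was 0.124, 0.0605 and 0.0690, each without RB array 4.

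Lists outside these themes stayed near 0 with RB. In RB against control the medians were 0.05 for p53 targets, 0.00 for apoptosis genes, 0.03 for secreted factors of senescence, 0.03 for interferon-stimulated genes, 0.00 for NF-kB targets, 0.05 for immediate early genes and 0.09 for TGF-beta targets. They were -0.07 for heat shock genes, 0.04 for cholesterol synthesis, -0.03 for glycolysis, -0.01 for oxidative phosphorylation, 0.00 for cytosolic ribosomal proteins, -0.03 for ribosome biogenesis, -0.10 for CDK inhibitors and -0.07 for the SMYD family with its RB partners. Markers of muscle, fat, cartilage, blood and epithelium had medians of 0.02, 0.05, 0.02, -0.02 and -0.02. Camera's adjusted p lay between 0.110 and 0.992 for these 20 lists. Single members did change: of 21 p53 targets TP53INP1 and ZMAT3 rose by 0.95 ± 0.13 and 0.45 ± 0.11, and POLH and DDB2 fell by 0.49 ± 0.10 and 0.41 ± 0.10, TP53INP1 in 1 of 3 probe sets. Of 28 ribosome biogenesis genes FBL and NOP58 fell by 0.48 ± 0.13 and 0.25 ± 0.06, and the list was called in RB plus SMYD2 against control, with a median of -0.10 (camera adjusted p = 0.00842, but adjusted p = 0.445 with an estimated correlation).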

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

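Of the tests of other explanations below, those for more RB1 transcript and for the histone genes, and the regroupings of arrays, were set before their results were seen. The tests on SMYD2 array 1 and on RNA quality were chosen after the result was seen.

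The difference made by RB leaned larger in the presence of SMYD2 for the cell cycle lists, by a test of the interaction at a preset correlation only. With an estimated correlation 0 of those 4 lists held (adjusted p = 0.529 to 0.979), and 0 genes were called, so the difference itself is not established. The medians were -0.25 for G2/M and mitosis, -0.21 for G1/S and DNA replication, -0.14 for homologous recombination and Fanconi repair and 0.13 for replication-dependent histones. SMYD2 array 1 is not the source of the G2/M lean, since without it the G2/M median was -0.35. With the ACTB 3′ to 5′ difference as a linear covariate the G2/M median was -0.31, so that measure did not account for the lean. RNA quality that 1 control gene does not capture was not tested. More RB1 transcript in the RB plus SMYD2 arrays may account for the lean and stays open. Within the 2 groups given RB, arrays with a higher RB1 signal had a lower G2/M mean (pooled within-group r = -0.747 over 8 arrays, exact within-group permutation p = 0.0868 from 576 orders; Spearman rho -0.667; r = -0.911 without the 2 arrays farthest from the median). An effect of SMYD2 on RB, which the design names, was not separated from this and stays open as well.

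SMYD2 array 1 stood apart from the other arrays, with a PC1 score of -46.1. Lower RNA quality is a candidate explanation. Over the other 15 arrays, those with a larger ACTB 3′ to 5′ difference lay lower on PC1 (Spearman rho = -0.729, permutation p = 0.0028; Pearson r = -0.895, permutation p = 2.0e-04; r = -0.756 without the 2 farthest arrays; rho = -0.524 with permutation p = 0.0827 within the 12 arrays numbered 3 to 5). Conditions shared by the arrays numbered 1 may contribute, since in 3 of the 3 other groups that array was the lowest on PC1. Transfected SMYD2 as such was argued against, because of the gaps between control and SMYD2 arrays numbered 3, 4 and 5 (12.4, -0.901 and -0.0788) only 1 reached 25% of the gap between those numbered 1.

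Of 17 replication-dependent histone transcripts 7 rose with RB while S-phase genes fell, and 10 did not pass. The shift of the list was lost with an estimated correlation (adjusted p = 0.164, and 0.109 with the replicate block as well). Of the 7 rising members, 4 rest on probe sets that the array design assigns to a single gene. Among them is the dim H1-4 (mean 4.74 over all arrays, limma adjusted p = 0.0452). The assignment was read from the probe set name, and binding of similar copies was not measured, so shared targets are not excluded. Histone genes did not rise as a whole: the 7 replication-independent ones had a median of -0.14, with 0 called higher. H2AZ1 and H2AZ2 were called lower (-0.23 ± 0.06 and -0.34 ± 0.09). The signs of both groups were the same under quantile and median scaling. The cause of the rise stays open, and the yield of transcripts without a poly(A) tail was not tested.

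Other regroupings of the same arrays were refitted, and their counts of calls were set beside the real one. For RB against control the real grouping (585) was the only 1 of 35 with as many, and the highest other called 0. For RB plus SMYD2 against control (1424) and RB against SMYD2 (642) it was also 1 of 35 with a highest other of 0, and for RB plus SMYD2 against SMYD2 (1422) it was 1 of 35 with a highest other of 226. No other grouping reached the real count for these 4. Each other grouping mixes the arrays of the 2 groups, so a real difference between them enters the spread and lowers the calls. A highest other of 0 is therefore not the count that chance alone would give. For SMYD2 against control, RB plus SMYD2 against RB and the interaction the real count was 0, which all 35, 35 and 100 regroupings reach by construction, so this says nothing about chance there. In SMYD2 against control, arrays numbered 1 and 3 against those numbered 4 and 5 called 2571, and in RB plus SMYD2 against RB the same division called 110. These high counts point to a structure of the samples that follows the replicate numbers. The highest for the interaction was 639, and whether that regrouping follows the numbers was not tested. Among the 8 regroupings that part each same-numbered pair, the highest other count was 0 in each of the 6 comparisons of 2 groups, and with the replicate block SMYD2 against control and RB plus SMYD2 against RB called 0.

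Single arrays far from the other 3 of their group were sought by Dixon's ratio in 280 groups of 4. There were 17, where chance alone gives about 1 in 20 (14), and 5 of them were SMYD2 array 1. On that array CRYBA2 read 6.81 (other SMYD2 arrays 5.03 to 5.17), ENTPD3 10.24 (8.81 to 8.94), PAK5 5.35, CPLX2 5.50 and the mean of the unfolded protein list 9.81. In control, CDK1 read 11.19 on array 1, CDKN1B 10.39 and CCND1 5.54 on array 3, and SLC16A4 4.75 on array 5. With RB, CDKN1A read 9.17 and SGO2 10.30 on array 3. With RB plus SMYD2, MND1 read 8.28 on array 3, SGO2 10.10 and MIF-AS1 5.80 on array 5, and the mean of the matrix list was 9.34 on array 1. With SMYD2, SKA1 read 8.36 and the mean of the matrix list 9.20 on array 3.

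Signal in data outside the comparisons came from probe sets with no gene symbol or several. Of these, limma called 34 in RB against control, 1 in RB plus SMYD2 against RB, 129 in RB plus SMYD2 against SMYD2, 133 in RB plus SMYD2 against control and 25 in RB against SMYD2.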

How the results depend on the processing

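No named gene reversed a called direction under the alternatives planned before the data were examined, and 81 values of uncalled genes changed sign. The counts of called genes below are for RB against control, RB plus SMYD2 against SMYD2, RB plus SMYD2 against control and RB against SMYD2, in that order. They moved to 1399, 2812, 2562 and 1831 with the replicate block, to 2296, 3141, 3687 and 1790 with array weights, and to 17, 80, 127 and 18 with a log2 difference of at least 1 required. With arrays numbered 1 left out they were 1089 and 1029 for the first and last. With only the arrays compared they were 748 for RB plus SMYD2 against SMYD2 and 193 for RB against SMYD2. Leaving out each array gave 286 to 984, 859 to 1753, 899 to 2032 and 304 to 888, and 0 throughout for the other 3 comparisons. Settings chosen after seeing the data gave 1427, 2472, 2646 and 1374 with the ACTB covariate, 2141, 3010, 3478 and 1921 with the block and without SMYD2 array 1, and 3033, 3784, 4559 and 2509 with the block and array weights.

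RB plus SMYD2 against RB rose from 0 to 72 genes (18 higher, 54 lower) with the block and array weights. Of the 54 lower genes, 22 belonged to the 3 cell cycle and repair lists, against 0.451 of the 72 if genes were independent. Genes of these lists vary together and already lay lower in this comparison, so the 0.451 does not measure chance. RB1 was among the 18 higher genes (0.95, limma adjusted p = 0.0429), which leaves more RB1 transcript open as an explanation. It rose to 1 (HMMR) with the block and without SMYD2 array 1. With every probe set tested, it and the interaction each rose to 1 (a MAP2K5 probe set); both genes were named after their values were seen. The cause was not tested for any of these.

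Lists called for SMYD2 against control (4) fell to 2 with quantile scaling, 2 without the lower 50% of genes, 2 with the mean of all probe sets, 1 with only the arrays compared, 1 with arrays numbered 1 left out, 1 with the ACTB covariate, 1 with the block and array weights, 0 with array weights, and 0 with the block and without SMYD2 array 1. With an estimated correlation, lists called fell from 9 to 4 (RB against control), 4 to 0 (SMYD2 against control), 4 to 3 (RB plus SMYD2 against RB), 10 to 4 (RB plus SMYD2 against SMYD2), 8 to 3 (RB plus SMYD2 against control), 4 to 0 (interaction) and 9 to 4 (RB against SMYD2). With the block too they were 5, 0, 0, 4, 3, 0 and 3. At the preset correlation, lists for RB plus SMYD2 against RB rose from 4 to 7 with the block and array weights. Leaving out each array gave 7 to 10, 0 to 7, 4 to 7, 7 to 10, 8 to 10, 2 to 5 and 9 to 11 lists, in the order of RB against control, SMYD2 against control, RB plus SMYD2 against RB, against SMYD2 and against control, the interaction, and RB against SMYD2. The correlation of the RB differences ran from 0.743 to 0.810, and that of the SMYD2 differences (0.226) from 0.0124 without SMYD2 array 1 to 0.311.

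Pairing of RB with SMYD2 arrays is unsettled: 3 of the 4 same-numbered pairs correlated above 0.1, those numbered 5 at -0.0772, and 5 of the 8 arrays correlated best with their own number. With the block and an estimated correlation 3 lists were called there in place of 4: the osteoblast list was gained (adjusted p = 0.0303), and G2/M and repair were lost (0.0744 and 0.117). At the preset correlation TGF-beta targets were gained (camera adjusted p = 0.0139), and RB1 passed (limma adjusted p = 0.0236). For the interaction the block called 0 as well. Taken per replicate number, the interaction of the list means was below 0 in 4 of 4 numbers for G1/S (-0.20, SD 0.14), G2/M (-0.23, SD 0.23) and CDK inhibitors (-0.08, SD 0.07). It was above 0 in 4 of 4 for the matrix list (0.07, SD 0.03) and the SMYD family list (0.08, SD 0.04). These lists were picked from the 29 tested because their 4 signs agreed. The repair list was below 0 in 3 of 4 numbers and the histone list in 1 of 4. With 29 lists and only 4 numbers, some lists would agree in sign by chance. This agreement therefore does not test the interaction. Leaving aside the fixed genes that did not pass in RB against SMYD2, the block changed the call of no other gene or list value given in the report. Dim genes limit what can be read, as RMA gives no background call.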

Other observations

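A MAP2K5 probe set, chosen after its values were seen, had the clearest difference in the comparison of the series title when every probe set was tested. MAP2K5 encodes MEK5, the kinase upstream of ERK5. The set read 6.73 ± 0.23 (SD, n = 4) in control, 7.26 ± 0.25 with RB, 6.28 ± 0.35 with SMYD2 and 4.75 ± 0.13 with both constructs. RB plus SMYD2 minus RB was -2.51 ± 0.16 on the log2 scale (limma adjusted p = 9.9e-07 over 41097 probe sets), and the interaction was -2.06 (limma adjusted p = 0.00336). The 4 arrays with both constructs lay between 4.61 and 4.92, and no array of the other groups was below 5.81. None of the other 5 MAP2K5 probe sets followed it. The brightest of them, at 7.05 with RB and 7.07 with both, differed by 0.02 ± 0.13. What the probe set detects was not tested.

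Between RB plus SMYD2 and RB the osteoblast list had a median of 0.00 (camera adjusted p = 0.869), with SPP1 at -0.42 ± 0.16, OMD at 0.39 ± 0.21, SOST at -0.37 ± 0.56 and MSX2 at -0.32 ± 0.18, none of which passed. The matrix list had a median of 0.02 (camera adjusted p = 0.789), with COL6A2 at 0.46 ± 0.24 and COL6A1 at 0.36 ± 0.12.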
